A study of Mus musculus with 12 samples.

How the data were processed

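RNA was extracted with Trizol from liver of male C57BL6 mice and measured on Affymetrix mouse arrays, with 1 array for each of 12 samples. The deposited values are log2 probe set summaries that the authors made with the Transcriptome Analysis Console, per the submitters' processing notes. Its version and the normalization and summarization method are not given in the sources used here. Values ran from 0.714 to 14.1 in the 12 arrays, and array medians lay close together, so that the values were taken as comparable between arrays and used as deposited. No array was left out, no 2 columns were identical, and the labels give no batch or date. The labels call the 3 arrays of a group biological replicates. The number of arrays limits the precision, and an exact permutation of 3 arrays against 3 cannot give a p below 0.1.

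Gene names came from the platform annotation. Of 41345 probe sets, 25335 were listed there, 23521 with 1 gene symbol and 1814 with several, and 16010 were not listed. Entrez identifiers of 23328 probe sets were matched to a GRCm38.p6 gene table, which was used for names only and changed 0 symbols. Probe sets with 1 symbol were reduced to 1 per gene, the one with the highest mean over the 12 arrays, which left 22180 genes, of which 1082 had more than 1 probe set. No filter on dim genes was applied. Control probe sets could not be told from other unlisted ones, and neither kind was tested among the named genes.

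Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with default settings, two-sided). A model with 4 group means was fitted to all 12 arrays, so that all groups shared 1 estimate of the spread for each gene (8 residual and 5.18 prior degrees of freedom). The 7 comparisons were the diet effect without extract, the extract effect on the high-fat diet, the extract effect on the low-fat diet, the diet effect with extract, the difference of both extract effects, the average diet effect and the average extract effect. Within each comparison p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes, and a gene passed the threshold at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale, first-named group minus second, and SE is the moderated standard error.

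Gene lists covered lipid, sterol, bile acid, amino acid and glucose metabolism, xenobiotic and stress responses, inflammation, the circadian clock, sex-biased liver genes, liver zones and the cell types that a piece of liver can hold. They were written from general knowledge, not taken from the study. Of 35 lists, 34 had at least 5 measured genes and were tested, and the list of erythroid markers had too few. Each was tested with camera (preset correlation of 0.01 between genes), which compares a list with all other genes, with the adjustment over the lists of a comparison. Beside it, camera was run with the correlation estimated for each list, and fry, which tests whether the genes of a list move on balance in one direction. In each list the genes past the threshold were counted over all genes and adjusted over the list alone. Values for a list in 1 array are the median over its genes of the difference from each gene's mean over the 12 arrays. Correlations between comparisons were taken across genes and set beside 100 draws in which residuals were assigned to the arrays at random, so that they hold no effect. The residuals of a group sum to 0, which widens the spread of the draws.

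Named genes followed a rule. For the diet effect without extract and the extract effect on each diet, it took the 5 genes per direction with the largest change among those past the threshold whose groups did not overlap, filled where needed by the genes of lowest p and without provisional names. It also took the 4 genes of lowest p in each called list, and a fixed panel of 35 genes, of which 30 had a probe set with 1 symbol and 5 were not used. For the other comparisons it took the 3 genes per direction of lowest adjusted p. The values of all genes so taken were computed, and a part of them is printed. The groups, comparisons, tests, lists, rule for named genes and alternatives were chosen before the data were examined.

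The procedure was tested on simulated data with 12 arrays and the spread of the real ones. For the extract effect on the high-fat diet, 90.8% of simulated 2-fold and 99.7% of simulated 4-fold changes passed the threshold, and 5.65% of the calls were unchanged genes. For the average extract effect these shares were 98.7%, 99.8% and 5.24%. Each draw held 200 changed genes and gave a mean of 205.3 calls for the extract effect on the high-fat diet, against 8 in the real data. More calls make the adjusted threshold easier to pass, so that these shares are not the power of the real comparisons. With no simulated change, a mean of 0.1 genes and 0.1 of 34 lists were called per draw, and a list with a simulated shift was called in 10 of 10 draws. Genes were simulated as independent of each other, while estimated correlations in the real lists reached 0.715 (sinusoidal endothelial markers). The rate of 0.1 lists therefore does not hold for the real lists. Other splits of the real arrays called a median of 6 to 9 lists.

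Alternatives were all probe sets whether named or not, leaving out the dimmest 25% or 50% of genes, quantile normalization, median centring, eBayes with trend and robust settings, array weights, only the arrays of the groups compared, the replicate number as a block, other thresholds, and leaving out each array in turn. A count of called genes was also taken for other splits of the same arrays, all 10 for groups of 3 and 100 drawn of 200 for the averages and the difference.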

Results

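Liver gene expression was measured in 12 RNA samples from male C57BL6 mice, with 1 Affymetrix array per sample. The mice ate a low-fat diet with 10% of energy from fat or a high-fat diet with 45%, either plain (control) or with 0.5% (w/w) of MSX, an extract of maple syrup enriched in phenols. The 4 groups of 3 arrays were low-fat control, low-fat MSX, high-fat control and high-fat MSX. Feeding lasted 12 weeks, from 6 to 18 weeks of age. The deposited log2 values covered 41345 probe sets with array medians between 4.68 and 4.75, and the correlation between any 2 arrays lay between 0.973 and 0.984. Across the 22180 named genes the first principal component held 14.9% of the variance and the next held 14.3%. On the first component the MSX arrays lay between 1.09 and 20.1 and the control arrays between −19.1 and −1.99. The p-values of single genes below measure differences against the spread between arrays labelled as biological replicates. Those of camera compare a list with all other genes. With the preset correlation they take no account of how far the genes of a list vary together between arrays.

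The comparison of the control groups addressed the response of the liver to the high-fat diet alone. Sqle, squalene epoxidase of cholesterol synthesis, was at 6.71 ± 0.27 on the log2 scale (SD, n = 3) on the high-fat diet and at 4.84 ± 0.24 on the low-fat diet, so that it rose by 1.88 (SE 0.21, adjusted p = 0.00519). Cyp51, a sterol demethylase of the same pathway, rose by 1.29 (SE 0.12, adjusted p = 0.000893). Themis, a gene known from T cell development, rose by 1.49 (SE 0.20, adjusted p = 0.0258). Igfbp2, an insulin-like growth factor binding protein secreted by the liver, fell by 1.29 (SE 0.15, adjusted p = 0.00519), from 11.03 ± 0.11 to 9.74 ± 0.08. These 4 genes, 3 higher and 1 lower, were the ones past the threshold of 22180 tested, and 1503 genes had an unadjusted p under 0.05 where chance alone gives 1109. Without low-fat control replicate 3 the count was 1, Cyp51, with Sqle and Igfbp2 no longer past the threshold. Themis lost its call without low-fat control replicate 1 or 3 or without any 1 of the 3 high-fat control arrays, with adjusted p up to 0.218.

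The camera test called 17 of 34 lists in the same comparison, 14 upward and 3 downward, and 0 of them held with an estimated correlation. Of the 19 measured genes of cholesterol synthesis and uptake, 2 rose and 0 fell over all genes tested, and 12 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 0.48 (camera adjusted p = 2.17e-22, and adjusted p = 0.0689 with an estimated correlation). Msmo1 and Hmgcs1, a pair of further enzymes of the pathway, had log2 fold changes of 1.53 (adjusted p = 0.0519) and 1.32 (adjusted p = 0.0761). Genes of inflammatory cytokines and signalling had a median of 0.39, with 0 of 26 past the threshold over all genes and 5 higher adjusted over the list alone (adjusted p = 0.0689 with an estimated correlation). Ccl2, a monocyte chemoattractant, had a log2 fold change of 0.81 (SE 0.20, adjusted p = 0.386). The acute phase proteins had a median of 0.30, with 0 of 22 past the threshold over all genes and 4 higher adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). Among them Lcn2 was at 2.13 (SE 0.59, adjusted p = 0.468). Antioxidant and conjugation enzymes (NRF2 targets) had a median of 0.23, with 0 of 27 past the threshold over all genes and 5 higher adjusted over the list alone (adjusted p = 0.0689 with an estimated correlation). The median of inflammatory cytokines and signalling was 0.26 without low-fat control replicate 2 or without high-fat control replicate 1. That of acute phase proteins was 0.17 without high-fat control replicate 2, and that of the antioxidant and conjugation enzymes (NRF2 targets) was 0.12 without low-fat control replicate 1.

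Male-biased liver genes, those with higher expression in male than in female mouse liver, had a median of −0.32 with the diet, with 0 of 18 past the threshold over all genes and 6 lower adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). The median of male-biased liver genes was −0.19 without low-fat control replicate 1. Genes of amino acid catabolism and urea cycle had a median of −0.21, with 0 of 22 past the threshold over all genes and 5 lower adjusted over the list alone (adjusted p = 0.106 with an estimated correlation). Got1, an aspartate aminotransferase, had a log2 fold change of −1.18 (SE 0.20, adjusted p = 0.103). With each array left out in turn, 9 of the 17 called lists kept their call.

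Several lists of other cell types lay high in 1 array of the control comparison. In high-fat control replicate 1 the stellate cell and matrix genes lay 0.68 above their mean over the 12 arrays (median over the genes). Each also above its own mean, the cholangiocyte markers lay at 0.53, the macrophage and Kupffer cell markers at 0.56 and the lymphocyte markers at 0.27. The stellate cell and matrix genes had a median log2 fold change of 0.41 on the high-fat diet (adjusted p = 0.202 with an estimated correlation), and 0.21 without that array, where the call was kept (camera adjusted p = 0.000832). The cholangiocyte markers had a median of 0.32 (adjusted p = 0.198 with an estimated correlation), and without that array the median was 0.10 and the call was lost (camera adjusted p = 0.104). The lymphocyte markers had a median of 0.24 (adjusted p = 0.106 with an estimated correlation), and 0.14 with the call lost without that array (camera adjusted p = 0.0533). For the macrophage and Kupffer cell markers the median was 0.35 (adjusted p = 0.45 with an estimated correlation). Without high-fat control replicate 1 it was 0.09 and the call was lost (camera adjusted p = 0.393), without replicate 2 it was 0.16, and without replicate 3 it was 0.63.

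**Figure D1:**
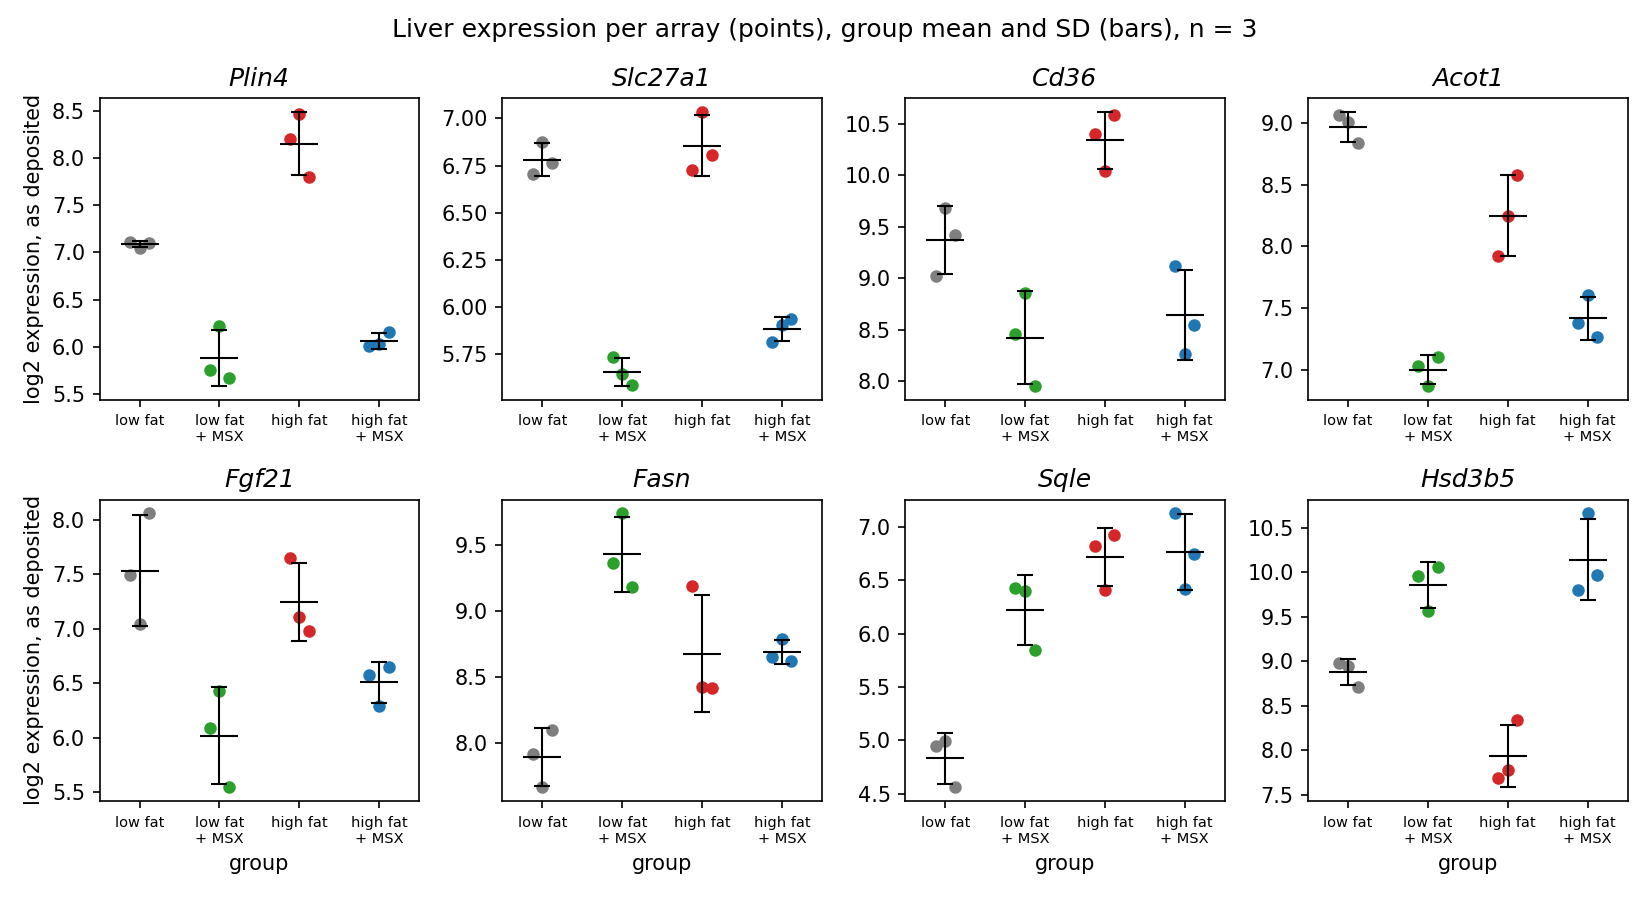
Expression of 8 genes on the log2 scale as deposited (y axis) in the 4 groups (x axis), with 1 point per array and bars for the group mean and SD (n = 3). Plin4 was at 7.09 and 8.16 in the control groups and at 5.88 and 6.06 in the MSX groups, on the low-fat and the high-fat diet.

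The comparison of high-fat MSX with high-fat control addressed the response to the extract on the high-fat diet. Plin4, a lipid droplet coat protein, fell by 2.10 on the log2 scale (SE 0.17, adjusted p = 0.000367), from 8.16 ± 0.34 to 6.06 ± 0.08 (SD, n = 3). Cd36, a fatty acid translocase, fell by 1.70 (SE 0.26, adjusted p = 0.0479), and Slc27a1, a fatty acid transport protein, fell by 0.97 (SE 0.11, adjusted p = 0.00783). Gpat3, an acyltransferase of glycerolipid synthesis, fell by 0.86 (SE 0.11, adjusted p = 0.0149), and its other probe set had a log2 fold change of −0.34. Themis fell by 1.47 (SE 0.20, adjusted p = 0.0202). Hsd3b5, a steroid-metabolising enzyme of male mouse liver, rose by 2.21 (SE 0.23, adjusted p = 0.00239), from 7.94 ± 0.35 to 10.14 ± 0.46. Bhlhe41, a repressor in the circadian clock, rose by 1.11 (SE 0.15, adjusted p = 0.0149), and F11, coagulation factor XI, rose by 1.03 (SE 0.15, adjusted p = 0.029). These 8 genes, 3 higher and 5 lower, were the ones past the threshold, and 1550 genes had an unadjusted p under 0.05.

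Plin4 and Hsd3b5 on the high-fat diet kept their calls with each of the 6 arrays left out. The count fell to 5 without high-fat control replicate 1 or 2, to 3 without replicate 3 and to 2 without high-fat MSX replicate 2. F11 and Themis lost their calls in each of the 6 cases. Cd36 lost its call except without high-fat MSX replicate 1, and Gpat3 except without high-fat MSX replicate 3. Bhlhe41 lost its call without high-fat control replicate 2 or 3 or high-fat MSX replicate 1 or 2, and Slc27a1 without high-fat MSX replicate 2. The highest adjusted p over these cases was 0.221.

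Of the 21 measured genes of triglyceride synthesis and lipid droplets, 0 rose and 1 fell over all genes, and 0 rose and 5 fell adjusted over the list alone. Their median was −0.23 (camera adjusted p = 8.03e-09), and the call held with an estimated correlation (adjusted p = 0.0263). Cidec, a lipid droplet fusion protein, and Pparg, a regulator of lipid storage, had log2 fold changes of −2.33 (SE 0.43, adjusted p = 0.118) and −1.12 (SE 0.19, adjusted p = 0.0897). The genes of fatty acid oxidation and PPAR alpha targets had a median of −0.18, with 0 of 30 past the threshold over all genes and 4 lower adjusted over the list alone (adjusted p = 0.151 with an estimated correlation). Pdk4, a kinase that restrains glucose oxidation, had a log2 fold change of −1.38 (SE 0.25, adjusted p = 0.107). Fatty acid uptake and lipoproteins had a median of −0.09, with 0 of 26 genes higher and 2 lower over all genes and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.154 with an estimated correlation). That median was −0.03 without high-fat control replicate 2, −0.14 without replicate 3 and −0.04 without high-fat MSX replicate 3. Genes of bile acid synthesis and transport had a median of 0.17, with 0 of 22 past the threshold over all genes and 5 higher adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). Abcg5 and Abcg8, which form a sterol exporter, had log2 fold changes of 0.54 (adjusted p = 0.199) and 0.64 (adjusted p = 0.196).

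Male-biased liver genes showed the largest list median in the extract comparison on the high-fat diet. Of 18 measured, 1 rose and 0 fell over all genes, 14 rose and 0 fell adjusted over the list alone, and all 18 had log2 fold changes above 0, with a median of 0.85 (camera adjusted p = 6.03e-22, and adjusted p = 0.0832 with an estimated correlation). Female-biased liver genes had a median of −0.30, with 0 of 18 past the threshold over all genes and 4 lower adjusted over the list alone (adjusted p = 0.0832 with an estimated correlation). By fry the adjusted p was 0.0303 for the male-biased and 0.0798 for the female-biased liver genes. Cyp2b13, a cytochrome of female mouse liver, had a log2 fold change of −2.19 (SE 0.42, adjusted p = 0.143). The median of female-biased liver genes was −0.09 without high-fat control replicate 1, in which they lay 0.45 above their mean over the arrays, and −0.51 without high-fat control replicate 2. Xenobiotic cytochromes and receptors had a median of −0.23, with 0 of 28 past the threshold over all genes and 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.154 with an estimated correlation). Interferon response genes had a median of −0.40, with 0 of 21 past the threshold over all genes and 1 lower adjusted over the list alone (adjusted p = 0.207 with an estimated correlation). Without high-fat MSX replicate 3 the median of interferon response genes was −0.19.

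Stellate cell and matrix genes had a median of −0.38 with the extract on the high-fat diet, with 0 of 20 past the threshold over all genes and 4 lower adjusted over the list alone (adjusted p = 0.154 with an estimated correlation). Col1a1, a collagen chain, had a log2 fold change of −1.09 (SE 0.36, adjusted p = 0.608). Without high-fat control replicate 1, in which stellate cell and matrix genes lay 0.68 above their mean over the arrays, the median was −0.17. Cholangiocyte markers, 0.53 above their mean in that array, had a median of −0.30 (adjusted p = 0.151 with an estimated correlation), and without it −0.08 with the call lost (camera adjusted p = 0.096). The camera test called 19 lists in this comparison, 5 upward and 14 downward, and 13 kept their call with each array left out in turn. Of the 19, only the list of triglyceride synthesis and lipid droplets held with an estimated correlation.

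The comparison of low-fat MSX with low-fat control addressed the same extract on the low-fat diet. Acot1, a cytosolic acyl-CoA thioesterase, fell by 1.96 on the log2 scale from 8.97 ± 0.12 in the controls (SD, n = 3), with an SE of 0.16 and adjusted p = 0.000286. Cyp4a31 and Cyp4a14, fatty acid hydroxylases, both fell by 1.60 (SE 0.16 with adjusted p = 0.00137, and SE 0.28 with adjusted p = 0.0492). Fgf21, a hormone of the fasting response, fell by 1.51 (SE 0.27, adjusted p = 0.0492), and Acot2, a mitochondrial thioesterase, fell by 1.49 (SE 0.25, adjusted p = 0.0442). Thrsp, a lipogenic protein, rose by 1.92 (SE 0.33, adjusted p = 0.0492), and Fasn, fatty acid synthase, rose by 1.54 (SE 0.21, adjusted p = 0.0127), from 7.89 ± 0.22 to 9.43 ± 0.28. Nsdhl, a sterol dehydrogenase of cholesterol synthesis, rose by 1.58 (SE 0.25, adjusted p = 0.0338). Cyp2c70, a bile acid hydroxylase of rodents, rose by 1.59 and Slc17a4, an anion transporter, rose by 1.47 (adjusted p = 0.0492 for both). Plin4 fell by 1.20 (SE 0.17, adjusted p = 0.0175). In all, 35 genes passed the threshold, 14 higher and 21 lower, and 1786 had an unadjusted p under 0.05.

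Acot1, Cyp4a31 and Cyp51 on the low-fat diet kept their calls with each of the 6 arrays left out, and each of the other 15 genes past the threshold that the rule for named genes takes here lost its call in at least 1 of the 6 cases. The count of 35 fell to 10, 6 and 9 without low-fat control replicate 1, 2 and 3, and to 12 and 14 without low-fat MSX replicate 1 and 2. It was 28 without low-fat MSX replicate 3.

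Of the 30 measured genes of fatty acid oxidation and PPAR alpha targets, 0 rose and 6 fell over all genes on the low-fat diet with extract, and 0 rose and 19 fell adjusted over the list alone. Of the 30, 29 had a log2 fold change below 0, and the median was −0.42 (camera adjusted p = 3.3e-28, and held at adjusted p = 0.0201 with an estimated correlation). Ehhadh, an enzyme of peroxisomal oxidation, fell by 0.91 (SE 0.15, adjusted p = 0.0338). Of 19 genes of cholesterol synthesis and uptake, 5 rose and 0 fell over all genes, and 11 rose and 0 fell adjusted over the list alone, with a median of 0.62 (adjusted p = 0.0765 with an estimated correlation). Among them Fdps rose by 1.44, Sqle by 1.39, Insig1 by 1.38 and Cyp51 by 1.11 (adjusted p between 0.00137 and 0.0332). Of 19 genes of fatty acid synthesis, 2 rose and 0 fell over all genes, and 14 rose and 0 fell adjusted over the list alone, with a median of 0.53 (adjusted p = 0.0759 with an estimated correlation).

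Of the 21 genes of triglyceride synthesis and lipid droplets on the low-fat diet with extract, 0 rose and 2 fell over all genes, Plin4 and G0s2, and 1 rose and 6 fell adjusted over the list alone. The median was −0.19 (adjusted p = 0.0768 with an estimated correlation), and −0.12 without low-fat MSX replicate 3. G0s2, an inhibitor of lipolysis, fell by 0.85 (SE 0.15, adjusted p = 0.0492), and its other probe set had a log2 fold change of −0.58. Male-biased liver genes had a median of 0.56, with 0 of 18 past the threshold over all genes and 6 higher adjusted over the list alone (adjusted p = 0.605 with an estimated correlation). Their median was 0.35 without low-fat control replicate 2 and 0.36 without low-fat MSX replicate 3. Interferon response genes had a median of −0.16, with 0 of 21 past the threshold over all genes and 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.746 with an estimated correlation). That median was −0.29 without low-fat control replicate 1, and −0.07 without replicate 3, where the call was lost (camera adjusted p = 0.176). Circadian clock genes had a median of 0.28, with 0 of 17 past the threshold over all genes and 2 higher adjusted over the list alone (adjusted p = 0.26 with an estimated correlation), and lost their call without low-fat MSX replicate 2 (camera adjusted p = 0.0509). Sinusoidal endothelial markers had a median of 0.26, with 14 of 15 genes above 0 and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000142, and adjusted p = 0.746 with an estimated correlation). Their median was 0.15 without low-fat control replicate 2. Stellate cell and matrix genes had a median of 0.20, with 18 of 20 genes above 0, 0 past the threshold over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.00634, and adjusted p = 0.746 with an estimated correlation). Their call was lost without low-fat control replicate 1 (camera adjusted p = 0.105) and without low-fat MSX replicate 3 (camera adjusted p = 0.0867). The camera test called 12 lists, 8 upward and 4 downward, and 6 kept their call with each array left out in turn. Of the 12, only the list of fatty acid oxidation and PPAR alpha targets held with an estimated correlation.

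**Figure D2:**
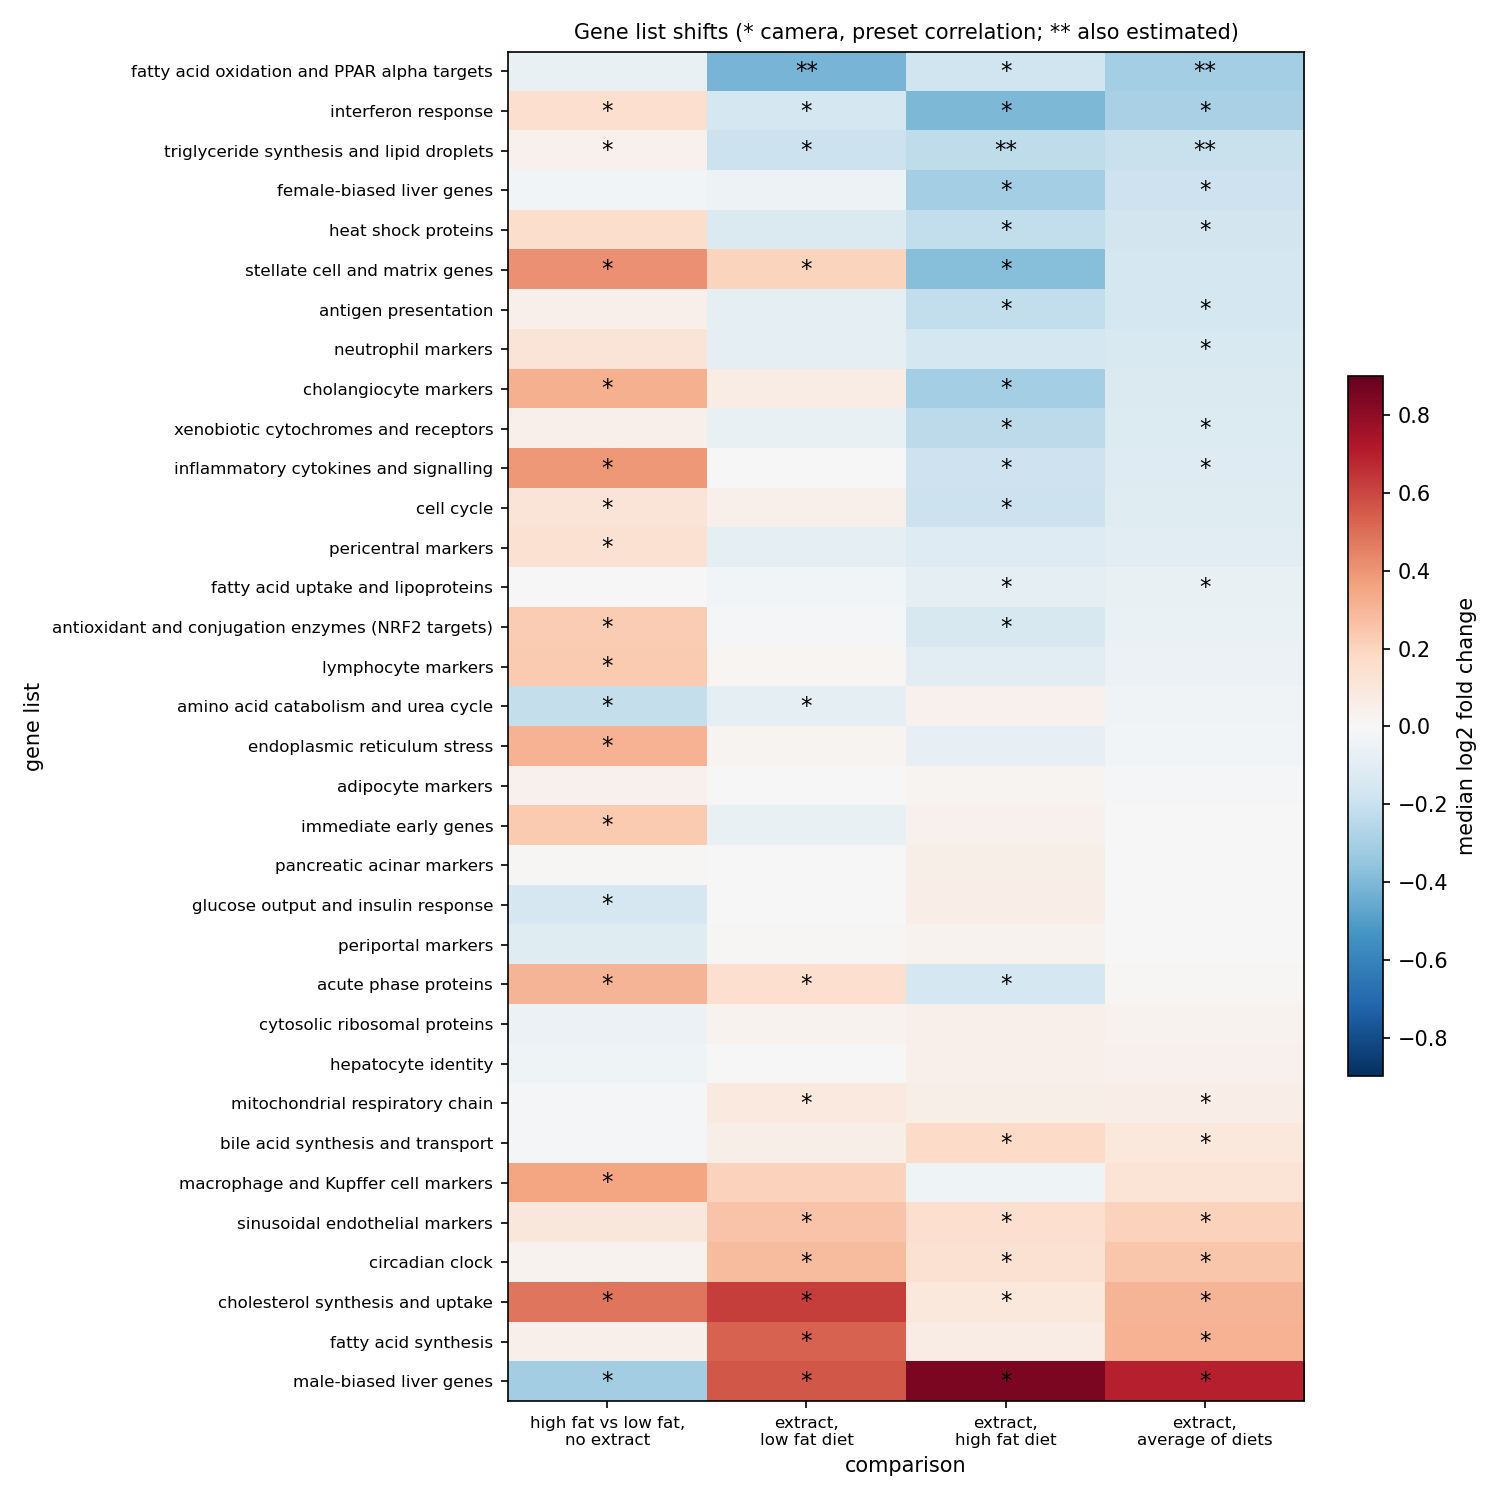
Median log2 fold change (colour) of each of 34 gene lists (y axis) in 4 comparisons (x axis), with 1 star where camera called the list with the preset correlation and a double star where it also did with an estimated correlation. Fatty acid oxidation and PPAR alpha targets lie at −0.42, −0.18 and −0.30, and male-biased liver genes at 0.56, 0.85 and 0.70, for the extract on the low-fat diet, on the high-fat diet and on average.

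The average of both extract effects, 6 arrays against 6, addressed what the extract changed across the diets. Plin4 fell by 1.65 on the log2 scale (SE 0.12, adjusted p = 7.87e-05), Slc27a1 fell by 1.05 (SE 0.08, adjusted p = 7.87e-05) and Acot1 fell by 1.39 (SE 0.11, adjusted p = 9e-05). Hsd3b5 rose by 1.59 (SE 0.16, adjusted p = 0.000748), F11 rose by 0.97 (SE 0.10, adjusted p = 0.00135) and Bhlhe41 rose by 0.88 (SE 0.10, adjusted p = 0.00198). These 6 genes kept their calls with each of the 12 arrays left out. In all, 58 genes passed the threshold, 26 higher and 32 lower, and 2143 had an unadjusted p under 0.05. The balance of directions turned with the scaling, with 38 higher and 32 lower after median centring and 30 higher and 48 lower after quantile normalization. The count was 36 without low-fat control replicate 2 and 34 without low-fat MSX replicate 1. Of 30 genes of fatty acid oxidation and PPAR alpha targets, 0 rose and 7 fell over all genes, and 0 rose and 20 fell adjusted over the list alone, with a median of −0.30. Of 21 genes of triglyceride synthesis and lipid droplets, 0 rose and 4 fell over all genes, and 2 rose and 8 fell adjusted over the list alone, with a median of −0.20. Both of these lists held with an estimated correlation (adjusted p = 0.0173 for each). Of 18 male-biased liver genes, 3 rose and 0 fell over all genes, and 12 rose and 0 fell adjusted over the list alone, with a median of 0.70 (adjusted p = 0.116 with an estimated correlation).

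On average over the diets, 4 of 19 genes of cholesterol synthesis and uptake rose and 0 fell over all genes, and 10 rose and 0 fell adjusted over the list alone, with a median of 0.30 (adjusted p = 0.126 with an estimated correlation). Their median was 0.62 on the low-fat diet and 0.09 on the high-fat diet. On the high-fat diet 15 of 19 were above 0, and 0 passed over all genes or adjusted over the list alone. There camera called the list upward with the preset correlation (adjusted p = 0.0375) but not with an estimated correlation (adjusted p = 0.564). Of 19 genes of fatty acid synthesis, 0 passed the threshold over all genes and 8 rose and 0 fell adjusted over the list alone, with a median of 0.31 (adjusted p = 0.126 with an estimated correlation). The median of fatty acid synthesis was 0.53 on the low-fat diet and 0.07 on the high-fat diet. On the high-fat diet 0 of 19 passed over all genes or adjusted over the list alone (camera adjusted p = 0.915). Of 17 circadian clock genes, 1 rose and 0 fell over all genes, and 4 rose and 1 fell adjusted over the list alone, with a median of 0.25 (adjusted p = 0.126 with an estimated correlation). Interferon response genes had a median of −0.29, with 0 of 21 higher and 1 lower over all genes and 1 higher and 9 lower adjusted over the list alone (adjusted p = 0.238 with an estimated correlation), and the median was −0.17 without low-fat control replicate 3. The camera test called 17 lists, 7 upward and 10 downward, and 10 kept their call with each array left out in turn. Of the 17, 2 held with an estimated correlation, those of fatty acid oxidation and PPAR alpha targets and of triglyceride synthesis and lipid droplets.

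The extract effects on the 2 diets share no array and so could be set against each other. Plin4, Slc27a1, Gpat3 and F11 passed the threshold on both diets and moved in the same direction, 4 genes where independent calls would share 0.0126. Both effects use the same estimate of the spread for each gene, so that their calls are not independent and chance may share more than that. Of the 35 genes past the threshold on the low-fat diet, 34 had the same sign on the high-fat diet, and all 8 past the threshold on the high-fat diet had the same sign on the low-fat diet. Across all 22180 genes the extract effects had a Pearson correlation of 0.208 and a Spearman correlation of 0.146, where genes are not independent replicates. Of 100 draws without any effect, 37 gave a Pearson value at least as far from their mean of −0.0168. The residuals of a group sum to 0, which makes these draws wide (SD 0.226). They therefore do not decide whether the correlation of the extract effects differs from 0.

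**Figure D3:**
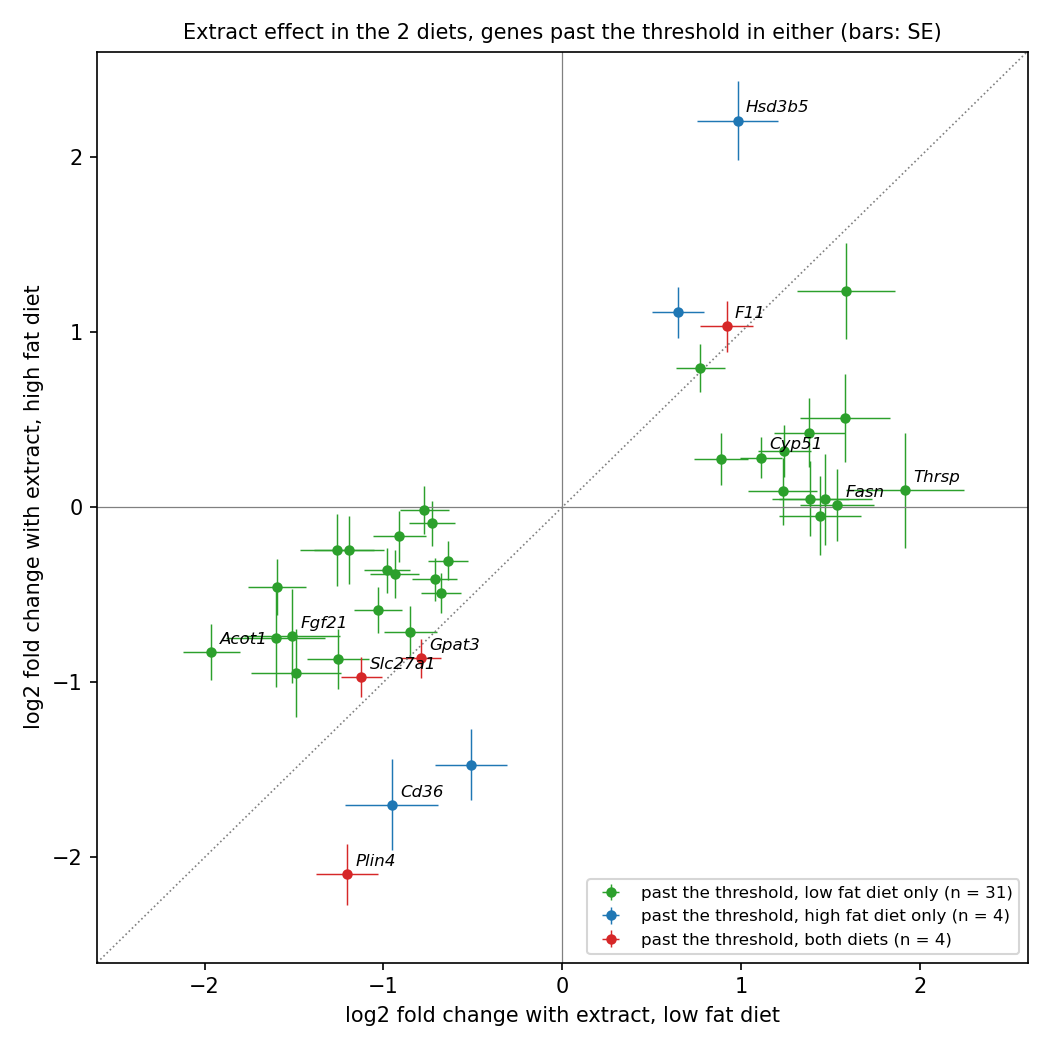
Log2 fold change with extract on the high-fat diet (y axis) against that on the low-fat diet (x axis) for the genes past the threshold on either diet, with bars for the SE, coloured by the diet on which the gene passed. Plin4 lies at −1.20 and −2.10 and Fasn at 1.54 and 0.01, on the low-fat and the high-fat diet.

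The difference of the extract effects, high-fat minus low-fat, tested whether the response to the extract depended on the diet. In limma 0 genes passed the threshold and 1130 had an unadjusted p under 0.05, with a lowest adjusted p of 0.664. Fasn had a difference of −1.53 (SE 0.29), with extract effects of 1.54 on the low-fat diet and 0.01 on the high-fat diet, and Cyp51 had a difference of −0.83 (SE 0.16), both with adjusted p = 0.664. The genes with the lowest p in the other direction were Csta1 at 1.65, Gm2788 at 1.18 and Igfbp2 at 1.09, and Mir669m-1 was at −1.45, again with adjusted p = 0.664. Without high-fat MSX replicate 1 the count was 1. The camera test called 13 lists with the preset correlation, and 0 with an estimated correlation. Of the 19 genes of fatty acid synthesis, 0 passed over all genes and 7 were lower adjusted over the list alone, with a median difference of −0.44 (adjusted p = 0.233 with an estimated correlation). Of 19 genes of cholesterol synthesis and uptake, 0 passed over all genes and 9 were lower adjusted over the list alone, with a median of −0.57 (adjusted p = 0.233 with an estimated correlation).

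The diet effect in mice that ate the extract, high-fat MSX minus low-fat MSX, passed the threshold for 0 genes in limma, with 1012 at an unadjusted p under 0.05. Egr1, an immediate early transcription factor, had a log2 fold change of 1.84 (SE 0.33), Acacb, an acetyl-CoA carboxylase, one of −1.18 (SE 0.21), Mir669m-1 one of −1.17 and Fabp5, a fatty acid binding protein, one of −0.83, each with adjusted p = 0.466. Klra9 and Snora34 were at 1.10 (adjusted p = 0.576) and 1.01 (adjusted p = 0.531). Without low-fat MSX replicate 2 the count was 1. Genes of fatty acid synthesis had a median of −0.42, with 0 of 19 past the threshold over all genes and 13 lower adjusted over the list alone (adjusted p = 0.0889 with an estimated correlation). Fatty acid oxidation and PPAR alpha targets had a median of 0.19, with 0 of 30 past the threshold over all genes and 1 higher adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). These 2 lists kept their camera call with each array left out, and the other 7 of the 9 called did not.

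Averaged over both diet effects, Cyp51 rose by 0.88 on the log2 scale (SE 0.08, adjusted p = 0.00142), Sqle rose by 1.21 (SE 0.15, adjusted p = 0.0224), Themis rose by 1.01 (SE 0.14, adjusted p = 0.0369) and Igfbp2 fell by 0.75 (SE 0.10, adjusted p = 0.0369) on the high-fat diets. Hmgcs1, named after its values were seen, rose by 1.02 and completed the 5 genes past the threshold, 4 higher and 1 lower, with 1318 at an unadjusted p under 0.05. Got1 and Gys2, a liver glycogen synthase, had log2 fold changes of −0.90 (adjusted p = 0.0896) and −0.50 (adjusted p = 0.0976). The average diet count of 5 fell to 1 without low-fat control replicate 1 or 3, high-fat control replicate 1 or 3, or high-fat MSX replicate 1 or 3, to 3 without low-fat control replicate 2 and to 2 without high-fat MSX replicate 2. Cyp51 kept its call with each of the 12 arrays left out. Sqle lost its call in the 6 cases with a count of 1. Igfbp2 kept its call only without 1 of the 3 low-fat MSX arrays. Themis kept its call only without low-fat control replicate 2 or low-fat MSX replicate 2. Of 19 genes of cholesterol synthesis and uptake, 3 rose and 0 fell over all genes, and 12 rose and 0 fell adjusted over the list alone, with a median of 0.32 (adjusted p = 0.0851 with an estimated correlation). The camera test called 18 lists, 13 upward and 5 downward, and 0 held with an estimated correlation.

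The extract effect on the high-fat diet was also set against the diet effect, to ask whether the extract moved genes opposite to the diet. Themis was the one gene past the threshold in both, higher with the diet and lower with the extract, and Cyp51 and Sqle passed the threshold upward both with the diet and with the extract on the low-fat diet. Across genes the correlation between the extract effect on the high-fat diet and the diet effect was −0.482 (Pearson), and draws without any effect gave −0.511 on average because the high-fat control arrays enter both with opposite signs. The covariance differed from the mean of the draws by −0.00135. For the extract on the low-fat diet the correlation with the diet effect was 0.460, and the draws gave 0.497 on average through the shared low-fat control arrays, with a covariance difference of 0.00124. Of 100 draws, 90 for the high-fat diet and 74 for the low-fat diet lay at least as far from their mean as the real value. Neither correlation therefore shows a relation to the diet effect beyond that from the shared arrays. Splitting the 3 control arrays of a group leaves fewer than 2 on a side, so that the sharing could not be avoided. Part of the shared calls of Themis, Cyp51 and Sqle may come from the shared arrays as well. The diet effects with and without extract share no array and had a correlation of 0.0510, and 75 of 100 draws without any effect lay at least as far from their mean. Because the residuals of a group sum to 0, these draws are wide and do not decide whether that correlation differs from 0.

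Of the 30 genes of a fixed panel, only Sqle, Fasn, Thrsp, Cd36, Cyp4a14 and Fgf21 passed the threshold in any of the 3 pairwise comparisons with control arrays. The genes that follow are examples of the others. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had log2 fold changes of −0.11 with the diet, −0.18 with the extract on the high-fat diet and −0.44 with the extract on the low-fat diet (SE 0.50 each, adjusted p between 0.866 and 0.985). G6pc, glucose-6-phosphatase, was at −0.69, 0.06 and 0.06 in the same order (SE 0.24). Tnf, an inflammatory cytokine, was at 0.25, −0.41 and −0.13 (SE 0.16), and Hmox1, heme oxygenase, at 0.66, −0.38 and 0.10 (SE 0.24). Cyp3a11, a xenobiotic cytochrome, was at −0.08, −0.97 and −0.43 (SE 0.19). Adgre1, a macrophage marker, was at 0.36, −0.02 and 0.46 (SE 0.28).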

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

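The 9 tests of explanations and the count of splits in this part were chosen after the result they weigh was seen, and the tests of a difference between the diets were planned. The difference of the extract effects between the diets, high-fat minus low-fat, was tested for each gene list, and 13 lists passed the threshold of camera with the preset correlation. Their median differences were −0.57 for cholesterol synthesis and uptake, −0.44 for fatty acid synthesis, 0.25 for fatty acid oxidation and PPAR alpha targets, −0.044 for antioxidant and conjugation enzymes (NRF2 targets), −0.32 for inflammatory cytokines and signalling, −0.24 for acute phase proteins, −0.31 for macrophage and Kupffer cell markers, −0.61 for stellate cell and matrix genes, −0.34 for cholangiocyte markers, −0.19 for cell cycle, 0.32 for male-biased liver genes, −0.079 for female-biased liver genes and 0.12 for amino acid catabolism and urea cycle. None of the 13 held with an estimated correlation, where the lowest adjusted p was 0.233. Of 100 splits of the arrays, 9 gave as many lists and the highest other count was 19, so that chance cannot be excluded for the number of lists. With each array left out in turn, 8 of the 13 kept their call. Where a call was lost, the highest camera adjusted p was 0.691 for macrophage and Kupffer cell markers, 0.0788 for cholangiocyte markers and 0.278 for female-biased liver genes, each without high-fat control replicate 1. It was 0.163 for antioxidant and conjugation enzymes (NRF2 targets) without low-fat MSX replicate 2, and 0.196 for amino acid catabolism and urea cycle without low-fat control replicate 1. Stellate cell and matrix genes kept their call at a median of −0.38 without high-fat control replicate 1.

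Among the 17824 probe sets with no symbol or several, which the named genes leave out, 2 passed the threshold for the extract effect on the low-fat diet and 5 for the average extract effect when all probe sets were tested together. What these probe sets measure was not analysed here.

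Fatty acid oxidation and PPAR alpha targets and lipid droplet genes were lower with the extract, by a median of −0.30 on average for the former. Fewer hepatocytes in the extract livers would lower hepatocyte genes alike, and the hepatocyte identity list had a median of 0.038 with an SD of 0.0867 over its genes, which argues against that explanation. A longer fast of the control animals cannot be told apart from an effect of the extract, because 7 glucose output genes that fasting induces went both ways (3 above 0 and 4 below, median −0.0013). A different time of day at collection stays open, since a score of clock genes (evening minus morning phase) was higher by 0.47 with the extract, with an exact permutation p of 0.015 within diets (400 arrangements). That p rests in part on Bhlhe41 (0.88), an evening gene already past the threshold for the extract in these data. Hlf of the evening genes (−0.0081) and Cry1 of the morning genes (0.34) went against such a shift, and all other members went with it. Against a different time of day as the whole cause stands low-fat MSX replicate 3, whose score of 1.31 lay within the low-fat controls (1.14 to 1.40) while its fatty acid oxidation and PPAR alpha targets were the lowest of the 12 arrays (−0.35 from their mean). A single array does not exclude it. An effect of the extract itself on these genes, which the design gives, stays open, and feeding times were not analysed here.

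Sex-biased genes shifted with the extract on the high-fat diet, with male-biased genes at a median of 0.85 and female-biased genes at −0.30, and neither list held with an estimated correlation (adjusted p = 0.0832 for each). By fry the male-biased genes passed (adjusted p = 0.0303) and the female-biased genes did not (adjusted p = 0.0798). Female animals among some of the 6 high-fat arrays are argued against, because no array stood apart by 2-fold in Xist or in the 3 Y-linked genes measured. Xist lay between 2.99 and 3.17 in these arrays, and the widest range was that of Eif2s3y at 0.552 (7.68 to 8.23). That 1 array sets the shift of the male-biased genes is argued against as well, since the smallest median was 0.70 (without high-fat MSX replicate 2) and the highest camera adjusted p was 4.48e-15. For the female-biased genes this cannot be told apart from an effect of the extract, because their median was −0.095 without high-fat control replicate 1 (camera adjusted p = 0.0198). An effect of the extract on the male-biased genes, which the design gives, stays open as a hypothesis.

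Stellate cell and matrix genes were higher on the high-fat diet without extract, by a median of 0.41 with 0 of 20 past the threshold over all genes and 2 higher adjusted over the list alone, and the list did not hold with an estimated correlation (adjusted p = 0.202). The median was 0.21 without high-fat control replicate 1 (camera adjusted p = 0.000832), so that how much of the shift that array sets cannot be told apart from the diet. A lower share of hepatocytes in that piece of liver is argued against as the whole cause, because it would raise the markers of all other cell types alike. In that array sinusoidal endothelial markers lay 0.086 above their mean (SD 0.197 over the other arrays), against 0.68 for the stellate cell and matrix genes. Other values of that array go with a lower share, since macrophage and Kupffer cell markers (0.56), lymphocyte markers (0.27) and cholangiocyte markers were at their highest of the 12 arrays and hepatocyte identity genes (−0.0643) at their lowest. More bile duct and portal tissue in that piece stays open and is consistent with cholangiocyte markers at 0.53 above their mean, where the next array was at 0.07 and the SD over the others was 0.0641. An effect of the high-fat diet on these genes, which the design names, stays open for the remaining shift.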

How the results depend on the processing

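Alternatives were planned, and none was added. Counts of genes, in the order diet effect without extract, extract effect on the high-fat diet, extract effect on the low-fat diet, average diet effect and average extract effect, were 4, 8, 35, 5 and 58. They were 1, 3, 10, 1 and 34 over all 41345 probe sets, and 11, 28, 77, 11 and 151 with trend and robust settings. Leaving out the dimmest 50% of genes gave 11, 19, 71, 11 and 173, where fewer genes are tested, and leaving out 25% gave 9 for both diet effects and 112 for the average extract effect. Adjusted p under 0.10 gave 11, 15, 61, 10 and 140. Unadjusted p under 0.05 with at least a 2-fold change gave 45, 58, 12 and 35 for the diet, the extract on the high-fat diet, the average diet and the average extract effect, and 13 and 78 for the diet effect with extract and the difference of extract effects, which were 0 in the other alternatives apart from arrays left out. Array weights gave 92 for the average extract effect. Only the groups compared gave 2 and 10 for the extract on the high-fat and low-fat diet, where fewer arrays estimate the spread. With 1 array left out, which also leaves fewer arrays, the ranges were 1 to 5 for the diet, 2 to 6 and 6 to 28 for the extract on the high-fat and low-fat diet, 0 to 1 for the diet with extract, 0 to 1 for the difference, 1 to 7 for the average diet and 34 to 63 for the average extract effect. Where no reason is given, the cause was not tested. The replicate number as a block gave 5 and 20 for the extract on the high-fat and low-fat diet. It leaves fold changes as they are by construction. Over all groups arrays of 1 replicate number were not alike (residual correlations between −0.126 and 0.112, mean 0.00234, with 2 of 18 pairs over 0.1). Between high-fat control and high-fat MSX, pairs of the same number were at 0.106, 0.0798 and 0.112, and the other pairs lay between −0.0885 and −0.00157. The residuals of a group sum to 0, so that high values in some pairs force low values in others. The other pairs are thus no separate support. Low-fat control replicate 2 and high-fat MSX replicate 3, of different number, were at 0.164. A pairing of high-fat control and high-fat MSX by number is neither shown nor excluded. Other counts stayed within 1.5 times. Lists called with an estimated correlation were 0, 1, 1, 0 and 2 in the order above and 0 for the diet with extract and the difference, against 17, 19, 12, 18 and 17, and 9 and 13, with the preset one. By fry they were 4, 2, 4, 5 and 8, and 1 and 0. With the diet these were cholesterol synthesis and uptake, antioxidant and conjugation enzymes, inflammatory cytokines and signalling, and amino acid catabolism and urea cycle. With the extract on the high-fat diet they were triglyceride synthesis and lipid droplets and male-biased liver genes. Low-fat diet calls were fatty acid oxidation and PPAR alpha targets, cholesterol synthesis and uptake, fatty acid synthesis, and triglyceride synthesis and lipid droplets. Medians of 3 called lists changed sign. That of triglyceride synthesis and lipid droplets with the diet (0.04) was at −0.00707 without the dimmest 50% of genes (camera adjusted p = 0.226), −0.00185 without high-fat control replicate 1 (0.127) and −0.00126 without replicate 3 (0.00658). That of acute phase proteins with the extract on the high-fat diet was at 0.00233 without high-fat control replicate 2 (0.423). That of cholesterol synthesis and uptake for the diet with extract was at −0.0298 without low-fat MSX replicate 3 (0.857) and −0.00401 without high-fat MSX replicate 1 (0.303). Of 650 pairs of a called named gene and an alternative, 447 kept the call, 203 lost it and 0 changed sign, and 12 of the 40 calls were kept throughout. The correlations between comparisons moved by less than the SD of their simulated values in each alternative, and that SD is wide (0.198 to 0.236). Background was not measured apart from signal, so that small changes in dim genes are not resolved.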

Other observations

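The counts over other splits of the arrays in this part were chosen after the results they test were seen, and the list tests were planned. Pericentral markers, genes of hepatocytes near the central vein, had a median log2 fold change of −0.10 for the average extract effect, where 0 of 14 rose and 1 fell over all genes, and 2 rose and 3 fell adjusted over the list alone. The one was Oat, ornithine aminotransferase, which fell by 0.71 on the low-fat diet (SE 0.12). Periportal markers had a median of 0.00 over 11 genes, with 0 past the threshold over all genes and 1 higher adjusted over the list alone. Sinusoidal endothelial markers had a median of 0.21 for the average extract effect, with 0 of 15 past the threshold over all genes and 0 adjusted over the list alone (adjusted p = 0.359 with an estimated correlation). Their median was 0.13 without low-fat control replicate 2 and 0.10 without high-fat control replicate 3. Heat shock proteins had a median of −0.17, with 0 of 11 past the threshold over all genes and 1 lower adjusted over the list alone (adjusted p = 0.342 with an estimated correlation), with a median of −0.30 without low-fat control replicate 2, and lost their call without replicate 3 (camera adjusted p = 0.152). Adipocyte markers and pancreatic acinar markers, which a piece of liver can hold from nearby tissue, had medians of −0.02 over 8 genes and −0.01 over 13 genes, and cytosolic ribosomal proteins had 0.03 over 27 genes.

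The counts were set against other splits of the same arrays. For the average extract effect, 1 of 100 splits (the real one) gave 58 genes and the highest other gave 1. The number of genes was thus far above that of all other splits drawn. Its share of 0.01 is the smallest that 100 splits can give, and it is not adjusted over the comparisons. For the lists 2 of 100 gave 17 or more and the highest other gave 19. That share is under 0.05 without adjustment over the comparisons, but another split gave more lists, so that chance is not excluded for the number of lists. The share says nothing of any single list, and 2 of the 17 held with an estimated correlation. For the average diet effect, 2 of 100 gave 5 or more genes (highest other 7) and 1 gave 18 lists (highest other 17). These shares are under 0.05 without adjustment over the comparisons. Since another split gave more genes and another nearly as many lists, chance is not excluded for either number. The shares say nothing of any single gene or list. The 5 genes fell to 1 without any of 6 arrays, and 0 of the 18 lists held with an estimated correlation. For the difference of extract effects, 100 of 100 splits gave at least 0 genes and the highest other gave 1. Groups of 3 allow only 10 splits, too few for a share under 0.05. Real and highest other counts of genes were 4 and 1 for the diet effect without extract, 8 and 0 for the extract on the high-fat diet, 35 and 2 for the extract on the low-fat diet, and 0 and 1 for the diet effect with extract. For lists they were 17 and 14, 19 and 15, 12 and 12, and 9 and 11, and the number of splits with as many was 1, 1, 2 and 3 of 10. Other splits called a median of 6 to 9 lists. Part of a real difference remains in such splits, and the cause of these calls was not tested.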
